A study of Homo sapiens with 18 samples.

How the data were processed

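Total RNA of MCF7 cells was extracted with Trizol, primed with oligo-dT carrying a T7 promoter and transcribed in vitro into biotinylated, fragmented cRNA, per the labels' protocols. The RNA was hybridized to Affymetrix arrays and the data were normalized by RMA, per the series' design text and the submitters' processing notes. The version and software of RMA, and which arrays were normalized together, are not given in the sources used here. The deposited table held log2 values made by the authors, 1 per probe set and array; all lay between 2.33 and 13.4, the range of log2 RMA output, and none was missing. RMA corrects background, equalizes the distribution of probe signals between arrays and summarizes probes per probe set, so values are relative to the other transcripts on the arrays and a loss of all mRNAs together is not seen. Every column of the table was matched to its sample by its label, and 0 columns of values were left unused.

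The table held 22277 probe sets, of which 62 were control probe sets, 19724 had 1 gene symbol in the platform annotation given, 568 had several and 1979 had none listed there. The gene IDs of 19707 probe sets with 1 symbol were found in the RefSeq gene table, through which 0 symbols changed. Probe sets with several symbols or none were left out. For each gene the probe set with the highest mean over the 18 arrays was kept, which gave 12165 genes, 4505 of them with more than 1 probe set. Probe sets of a gene could differ: of 132 named genes with several, all had the same sign in 79 with actinomycin D and 90 with triptolide at 6 h. Genes whose probe sets differed are not all marked below. No genome build was named, so no coordinates or gene lengths were used.

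Samples were grouped by drug and time from their titles into 9 groups of 2. A linear model with 1 mean per group was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (9 residual degrees of freedom, 8.65 prior degrees of freedom), with default eBayes settings, contrasts between groups, and Benjamini-Hochberg adjustment within each contrast. Genes were called at an adjusted p under 0.05. Contrasts were each drug against DMSO, triptolide against actinomycin D, their means over the 3 times, 6 h against 2 h within each treatment, and the change of each drug's effect from 2 to 6 h. Intervals of differences are 95% intervals from limma. The median SE of a difference between 2 groups was 0.149. No read depth applies to arrays, and their number limited the precision.

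The choices above, the gene lists, the rule for named genes and most alternatives were set before the data were examined. Named genes were, for each drug against DMSO and for triptolide against actinomycin D, the 8 largest rises and 8 largest falls at 6 h and the 4 and 4 at 2 h among genes past the threshold whose arrays did not overlap between the groups, from probe sets with a single symbol; fewer were named where fewer passed. To these were added, for each list discussed, the 2 to 4 members with the largest change at 6 h past the threshold, or the 2 with the largest change where fewer passed, and always MCL1, BCL2L1, BCL2, MYC, JUN, FOS, ESR1, GATA3, ERCC3, POLR2A, HEXIM1, CDKN1A, MDM2, CCND1, GAPDH and ACTB. Y-linked genes and XIST were not named.

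Of 49 gene lists, 47 had at least 3 measured genes and were tested with limma's camera at a preset correlation between genes of 0.01, with camera at an estimated correlation, and with fry; the other 2 were not tested. Benjamini-Hochberg adjustment ran over the 47 lists of a contrast. With the estimated correlation no list passed in the comparisons of actinomycin D with DMSO or of the drugs with each other, and with triptolide TGF-beta and BMP feedback genes passed at 4 h (adjusted p = 0.0386) and at 6 h and immediate early genes at 6 h. By fry, which asks whether a list's genes move one way without comparing them with other genes, 29, 25 and 31 lists passed with actinomycin D at 2, 4 and 6 h, 32, 23 and 27 with triptolide, and 0 between the drugs at any time, where its test for change in either direction passed for 1, 2 and 15. Array measures were compared by exact permutation. Shared responses were compared with 50 simulations of unchanged groups against shared controls and with splits of the DMSO arrays into sets of 3.

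Scripts were tested on simulated data for the comparison of actinomycin D with DMSO at 6 h, with 12165 genes of which 200 were changed, 50 per size. Recovery was 32% at 0.5 log2 units, 98% at 1 and 100% at 2 and at 4, with 5 false calls (2.94%). A list of 30 genes shifted by -0.3 was found (adjusted p = 1.43e-15), and 0 of 40 other lists were called. Noise was drawn independently for each gene and array. False calls from genes that vary together or from shifts of whole arrays were therefore not tested.

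Alternatives tried were centring on ribosomal protein genes, on poly-A controls or on the original hybridization controls, the mean of a gene's probe sets, no probe sets ending in _x_at or _s_at, only genes above the median level of 5.09, a trend and robust settings in eBayes, array weights, only the arrays compared, all 6 DMSO arrays as controls, a threshold of 2-fold, the replicate number as a block, fry, an estimated correlation, and each array left out in turn. Centring on the r2 hybridization controls, quantile normalization of the probe sets, the ACTB 3′ to 5′ difference as a covariate, and leaving out 2 doubted arrays were chosen after seeing the data. Taking log2 was not run, since the values already were on that scale.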

Results

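Transcript levels were measured in MCF7 cells, an established estrogen receptor-positive human breast cancer line, after treatment with 1 of 2 transcription inhibitors or with the solvent DMSO. Actinomycin D, a DNA intercalator that blocks elongating RNA polymerases, was given at 2.5 uM. Triptolide, a diterpenoid that binds the ERCC3 (XPB) subunit of the transcription factor TFIIH, was given at 500 nM. Cells were taken at 2, 4 and 6 h, which gave 9 groups of 2 arrays and 18 arrays in all. Each array reported 22277 Affymetrix probe sets as RMA values on the log2 scale, between 2.33 and 13.4. After 1 probe set was kept per gene, 12165 genes were tested. Correlations across genes between the 2 arrays of a group ran from 0.986 (triptolide 2 h) to 0.995, although genes are not independent replicates. The number of arrays limited the precision, and the median 95% interval of a difference between 2 groups reached 0.314 log2 units to either side. All levels were relative to the other transcripts on the array, so a loss shared by all mRNAs would not appear in them. The labels do not say whether the 2 arrays of a group came from separate cultures. The p-values therefore measured only the spread between these samples, which may be technical.

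The first comparison asked which transcripts stood lower or higher after actinomycin D than in DMSO cells of the same time. PPM1D, which encodes a phosphatase that acts on the p53 pathway, had the largest fall at 6 h, from 9.23 ± 0.098 to 3.84 ± 0.053 log2 units (mean ± SD, n = 2 each), or 42-fold. The amino acid transporter gene SLC38A2 fell 17.5-fold, the transcription factor gene ZNF217 16.7-fold, and IER3, a stress-induced immediate early gene, 12.8-fold. Signal over background was not given, and the levels of PPM1D (3.84) and ZNF217 (3.90) with the drug lay among those of the dimmest genes (mean levels of 3.18 to 3.98 in the 3 dimmest of 10 groups), so these folds and ranks hold for array values alone. Rises were smaller, and the largest, that of the ribosomal protein gene RPL37A, was 2.1-fold. In limma's test 2067 of the 12165 genes passed at 6 h, 1198 lower and 869 higher. Of these, 539 lower and 1 higher differed at least 2-fold. The rises rested on single arrays, with fewer without replicate 2 of actinomycin D 6 h or replicate 1 of DMSO 6 h.

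The largest falls at 6 h, in log2 units, were those of PPM1D at -5.39 (SE 0.183, adjusted p = 2.31e-12) and SLC38A2 at -4.13 (SE 0.264, adjusted p = 6.29e-09). ZNF217 followed at -4.06 (SE 0.281, adjusted p = 1.29e-08), and ZC3H4, whose product restrains transcription outside genes, at -4.05. The homeobox gene ADNP was at -4.04, the ubiquitin ligase gene RNF139 at -4.04, TSC22D1, a gene responsive to TGF-beta, at -3.80 and IER3 at -3.67. The largest rises were those of RPL37A at 1.07 (SE 0.262, adjusted p = 0.00893) and the ER stress factor gene ATF6B at 0.95 (SE 0.227, adjusted p = 0.00773). NFATC4 rose by 0.89, the coagulation factor gene F5 and FEZF2 by 0.87, the guidance factor gene SEMA3A and ANAPC15 by 0.84 and the aquaporin gene AQP3 by 0.83. NFATC4, F5 and AQP3 had lowest probe sets at 0.02, 0.25 and 0.01. Without probe sets ending in _x_at or _s_at, RPL37A stood at -2.27 and ATF6B at -0.20, and the mean of its probe sets put RPL37A at -0.60. At 2 h PPM1D was already at -4.08 (SE 0.183, adjusted p = 2.81e-10), IER3 at -3.82, ZNF217 at -3.39 and DNAJB9, a co-chaperone of the endoplasmic reticulum, at -2.99. Rises at 2 h were led by RPL37A at 1.36, LRRN3 at 1.19, the sialyltransferase gene ST3GAL6 at 1.07 and the antisense transcript PDCD4-AS1 at 1.06.

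Actinomycin D was followed by 2674 calls at 2 h (1878 lower, 796 higher) and 1157 at 4 h (1040 lower, 117 higher). Over the mean of the 3 times 5003 genes passed (2297 lower, 2706 higher). Of the genes higher at 2 h, 64.8% lay below the median gene level, against 57.3% at 4 h and 50.9% at 6 h, and of the genes lower at 2, 4 and 6 h 79.3%, 72.6% and 77.4% lay above it. The share of calls that were higher was 29.8% at 2 h, 10.1% at 4 h, 42% at 6 h and 54.1% over the 3 times, and it depended on single arrays and on how the arrays were scaled. It was 12.8% at 2 h without replicate 2 of actinomycin D 2 h, 13.9% at 6 h without replicate 2 of actinomycin D 6 h and 17.4% at 6 h without 2 doubted arrays (triptolide 2 h replicate 2 and actinomycin D 6 h replicate 2). With a covariate for the ACTB 3′ to 5′ difference, a measure of RNA quality, it was 4.45% at 2 h and 29% over the 3 times. Poly-A control centring gave 1.57% at 2 h, 1.42% at 4 h, 0.922% at 6 h and 2.19% over the 3 times. The r2 hybridization controls gave 0.019%, 0.0649%, 0.0603% and 0.011% for the same 4 contrasts. Ribosomal protein centring gave 1.65% at 4 h, 11.9% at 6 h and 33% over the 3 times, and quantile normalization of probe sets gave 52.5% at 2 h and 28.9% at 4 h. The median change of all genes, -0.02, 0.05 and 0.15 at 2, 4 and 6 h as deposited, became -0.36, -0.09 and -0.13 with the poly-A controls and -0.77, -0.25 and -0.18 with the r2 controls. With the original hybridization controls it became 0.09, -0.32 and 1.29, and 0 genes passed limma's test at each single time. The ACTB covariate left 382 calls at 2 h. Leaving out single arrays lowered the counts at 2, 4 and 6 h.

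**Figure D1:**
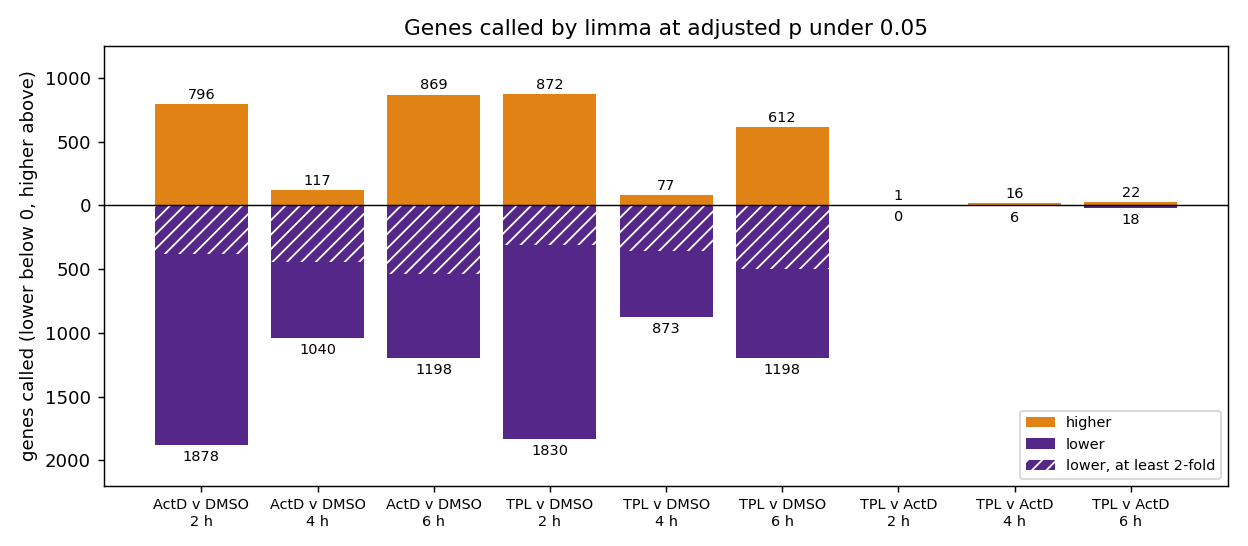
Number of genes called higher (above 0) and lower (below 0) in limma's test for each comparison, with the hatched part showing genes lower by at least 2-fold. Of the 1198 genes lower at 6 h with each drug, 539 with actinomycin D and 501 with triptolide were lower by at least 2-fold.

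Triptolide was set against the same DMSO arrays with the same question. At 6 h SLC38A2 had the largest fall, 23.4-fold, from 9.34 ± 0.127 to 4.80 ± 0.37 log2 units (mean ± SD, n = 2 each). TSC22D1 fell 22-fold, ZNF217 21.8-fold, ADNP 17.7-fold, PPM1D 16.6-fold and IER3 16.1-fold. They were followed by TOB1, an antiproliferative gene, at 15.5-fold and the lipid droplet gene HILPDA at 14.7-fold, where the levels of HILPDA (3.34) and ZNF217 (3.52) with the drug again lay among those of the dimmest genes. The largest rise was again that of RPL37A, 2.83-fold. In limma's test 1810 genes passed at 6 h, 1198 lower and 612 higher, with 501 lower and 7 higher by at least 2-fold. Fewer were higher without replicate 2 of triptolide 6 h or of DMSO 6 h.

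In log2 units the falls at 6 h were -4.55 for SLC38A2 (SE 0.264, adjusted p = 1.58e-09), -4.46 for TSC22D1, -4.45 for ZNF217 and -4.15 for ADNP. PPM1D was at -4.06 (SE 0.183, adjusted p = 9.04e-11), IER3 at -4.01, TOB1 at -3.95 and HILPDA at -3.87. Rises at 6 h were those of RPL37A at 1.5 (SE 0.262, adjusted p = 0.000502), the thiopurine methyltransferase gene TPMT at 1.10, the muscle gene NEB at 1.10 and WBP2 at 1.07. The coronin gene CORO1B rose by 1.07, METRN by 1.03, the mitochondrial citrate carrier gene SLC25A1 by 1.01 and NFATC4 by 0.999. The other NEB probe set was at 0.06. Without probe sets ending in _x_at or _s_at, RPL37A was at -2.28, and TPMT at 0.25 (adjusted p = 0.237) and NFATC4 at 0.06 (adjusted p = 0.846) no longer passed. At 2 h IER3 was at -4.02 (SE 0.237, adjusted p = 1.4e-08), DNAJB9 at -2.92, ZNF217 at -2.78 and BAMBI, a decoy receptor for TGF-beta, at -2.75. The rises at 2 h were led by the myosin gene MYH4 at 1.10, MFAP5 at 1.09, RPL37A at 1.04 and the kinase gene DAPK1 at 1.04.

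Counts after triptolide were 2702 at 2 h (1830 lower, 872 higher), 950 at 4 h (873 lower, 77 higher) and 3475 over the mean of the 3 times (2030 lower, 1445 higher). Genes below the median level made up 58.1%, 53.2% and 26.8% of the rises at 2, 4 and 6 h. The share of calls that were higher was 32.3% at 2 h, 8.11% at 4 h, 33.8% at 6 h and 41.6% over the 3 times. It was 16.1% at 2 h without replicate 2 of triptolide 2 h, 15.1% at 6 h without replicate 2 of triptolide 6 h and 2.8% at 2 h with the ACTB covariate. For these 4 contrasts it was 1.98%, 0.741%, 12.5% and 2.88% with the poly-A controls and 0.337%, 0.0867%, 0.0257% and 0.0108% with the r2 controls. Ribosomal protein centring gave 1.86% at 4 h, 12% at 6 h and 14.7% over the 3 times. Quantile normalization of probe sets gave 52.6%, 21.4%, 45.9% and 59% for the 4 contrasts. The median change of all genes, -0.0036, 0.06 and 0.06 as deposited, became -0.35, -0.06 and 0.02 with the poly-A controls and -0.44, -0.20 and -0.55 with the r2 controls. With the original hybridization controls it became 0.21, -0.29 and -0.96, and 0 genes passed limma's test at each single time. Ribosomal protein centring moved it to -0.06 at 6 h. The count at 2 h rested on single arrays, with 415 calls without replicate 2 of triptolide 2 h and 4115 without replicate 1. It was 357 without the doubted arrays, 384 with only the arrays compared and 214 with the ACTB covariate.

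Several regulators chosen in advance had lower transcript levels with both drugs at all 3 times. MCL1, an antiapoptotic BCL2 family gene, was at -1.25, -1.70 and -2.34 at 2, 4 and 6 h with actinomycin D and at -1.43, -1.63 and -2.52 with triptolide (adjusted p = 4.97e-07 and 2.2e-07 at 6 h). MYC was at -1.11, -1.13 and -1.03 with actinomycin D and at -0.89, -1.09 and -1.43 with triptolide. GATA3, a luminal transcription factor, was at -0.69, -1.53 and -1.75 and at -0.81, -1.98 and -2.45 in the same order. HEXIM1, an inhibitor of the elongation kinase P-TEFb, was at -0.78, -1.14 and -1.04 and at -0.61, -1.01 and -1.47. MCL1's 5 probe sets ran from -3.72 to -0.22 with actinomycin D at 6 h. Without probe sets ending in _s_at or _x_at MCL1 was at 0.13 with actinomycin D and 0.04 with triptolide at 2 h, and at -0.45 (adjusted p = 0.0764) and -0.38 (adjusted p = 0.159) at 6 h.

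Other regulators passed at fewer times. BCL2 fell with actinomycin D, at -0.50, -0.63 and -1.04, while its changes with triptolide were -0.02, -0.07 and -0.07 (adjusted p = 0.839 at 6 h). CDKN1A, the cell cycle inhibitor p21, fell at 2 and 4 h, to -0.65 and -0.62 with actinomycin D and -0.89 and -0.60 with triptolide. Its changes at 6 h were -0.43 (adjusted p = 0.0652) and -0.35 (adjusted p = 0.158). FOS fell at 2 h, by 0.91 with actinomycin D and by 0.69 with triptolide. JUN rose at 2 h by 0.74 (adjusted p = 0.0148) and 0.65 (adjusted p = 0.0291), a rise that turned to -0.02 with actinomycin D under r2 centring. Of the transcription machinery, POLR2A, the largest subunit of RNA polymerase II, was at -0.43 at 2 h with actinomycin D and ERCC3 at -0.61 at 2 h and -0.66 at 6 h. ESR1, the estrogen receptor gene, was at -0.60 at 2 h, and MDM2 rose by 0.65 at 6 h (adjusted p = 0.0417), both with actinomycin D. As means of their probe sets ESR1 and POLR2A were each at 0.07 at 2 h, and MDM2 was at -0.0051 without probe sets ending in _x_at or _s_at. With triptolide CCND1 fell at 4 h, by 0.56 (adjusted p = 0.039), and ESR1, ERCC3, POLR2A and MDM2 passed at no time. BCL2L1 did not pass with either drug. Without probe sets ending in _x_at or _s_at it was at -0.46 at 2 h (adjusted p = 0.0349) and -0.70 at 6 h (adjusted p = 0.00297) with actinomycin D. GAPDH and ACTB passed at no time with either drug, at 0.01 (adjusted p = 0.941) and 0.14 (adjusted p = 0.423) with actinomycin D at 6 h. Under r2 centring GAPDH was at -0.68 with actinomycin D at 2 h and -0.57 with triptolide at 6 h, and ACTB at -0.60 and -0.44.

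**Figure D2:**
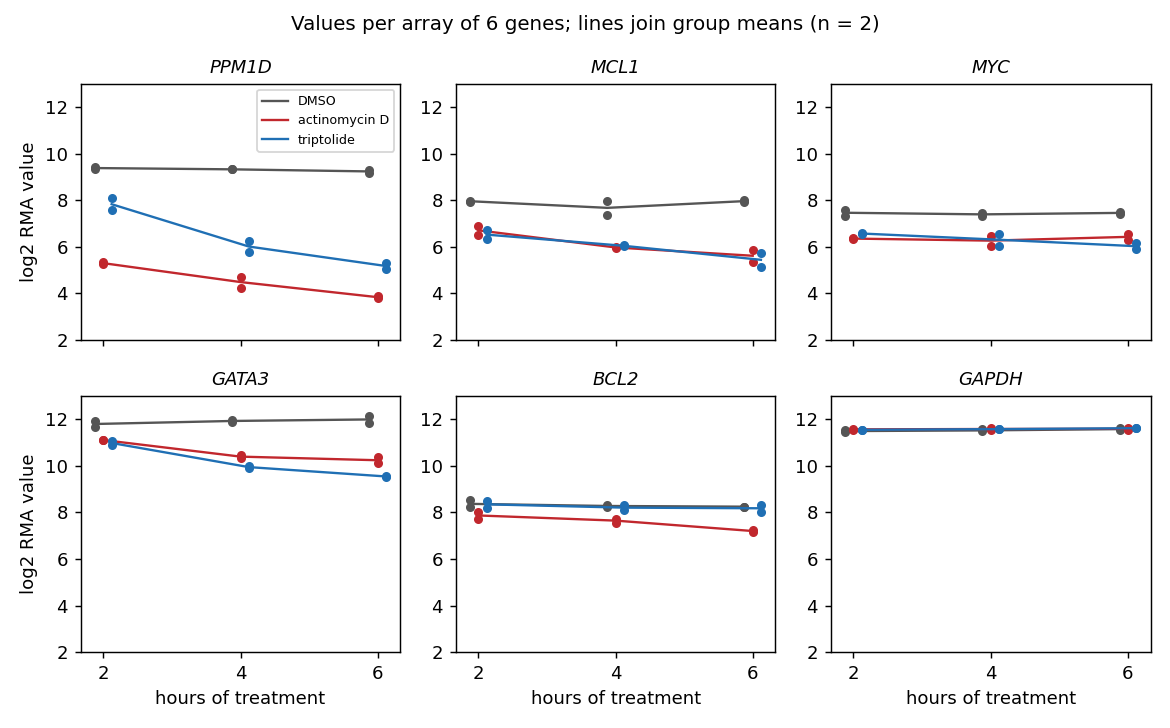
Log2 RMA values of PPM1D, MCL1, MYC, GATA3, BCL2 and GAPDH on each array at 2, 4 and 6 h, with points for arrays and lines joining the group means (n = 2). PPM1D was at 9.23 in DMSO, 3.84 with actinomycin D and 5.18 with triptolide at 6 h, and GAPDH group means lay between 11.5 and 11.6 in all 3 treatments.

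Gene lists fixed in advance were compared with the other genes measured at 6 h. Their directions are relative to those genes and do not change when all values of an array are shifted alike. In what follows paired values give actinomycin D before triptolide. Luminal transcription factor genes stood lower with both drugs, with 9 and 8 of 17 lower and none higher, or 9 lower, and 8 lower and 1 higher, adjusted over the list alone. Besides ZNF217, TFAP2C was at -3.62 and -3.31, the epithelial factor GRHL2 at -2.40 with actinomycin D and the secretory factor XBP1 at -2.57 with triptolide. The other probe set of TFAP2C was at -0.33 and -0.37. Camera gave luminal factors adjusted p = 2.29e-09 and 4.39e-08 (adjusted p = 0.0891 and 0.0875 with an estimated correlation). Of 14 TGF-beta and BMP feedback genes 7 fell with each drug, 7 and 8 adjusted over the list alone. BAMBI was at -3.41 and -3.51, ID2 at -2.70 and -2.86 and ID3 at -1.47 and -1.88. Their camera adjusted p was 4.48e-05 and 1.91e-06 (adjusted p = 0.0891 and 0.0411 with an estimated correlation). Immediate early genes, 39 in all, held 14 and 15 that fell, 15 and 17 adjusted over the list alone, and with actinomycin D 1 that rose, 3 adjusted over the list alone. IER3 led them, before TOB1 at -3.48 and -3.95 and ID2. This list had camera adjusted p = 5.74e-05 and 3.1e-09 (adjusted p = 0.139 and 0.0411 with an estimated correlation).

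Zinc-finger, p53, Wnt and death receptor genes also stood lower than other genes. Of 234 C2H2 zinc-finger genes, 50 fell and 4 rose with actinomycin D and 70 fell and 2 rose with triptolide. Adjusted over the list alone, these were 55 and 6, and 78 and 3. ZNF267 was at -2.24 and -2.48, next to ZNF217. Zinc-finger genes had camera adjusted p = 1.25e-05 and 6.3e-10 (adjusted p = 0.217 and 0.0959 with an estimated correlation). Of 23 p53 target genes 6 and 7 fell, 9 and 7 adjusted over the list alone, and 1 rose with actinomycin D. After PPM1D came PLK2 at -1.15 and -1.27 and TIGAR at -1.09 and -0.96. The p53 list had camera adjusted p = 0.0016 and 0.00271 (adjusted p = 0.139 and 0.115 with an estimated correlation). Wnt pathway genes, 18 in all, held 5 that fell with each drug, 7 and 5 adjusted over the list alone, and 1 that rose with actinomycin D. The Wnt antagonist gene DKK1 was at -1.80 and -1.87, MYC as above and the receptor gene FZD5 at -1.19 and -1.76, but at 0.32 and 0.10 without probe sets ending in _x_at or _s_at. Wnt genes had camera adjusted p = 0.0105 and 0.00048 (adjusted p = 0.166 and 0.0875 with an estimated correlation). Among 12 inhibitor of apoptosis and death receptor genes 4 fell with each drug, 4 adjusted over the list alone. The adaptor gene FADD was at -2.42 and -2.47, the receptor gene TNFRSF1A at -1.002 and -1.16 and BIRC2 at -0.85 and -0.87. Death receptor genes had camera adjusted p = 0.00102 and 0.00271 (adjusted p = 0.252 and 0.266 with an estimated correlation).

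Within the transcription machinery, part of each list fell. Among 24 Mediator subunit genes 7 and 9 fell and 1 rose with each drug, with equal counts adjusted over the list alone. MED17 was at -2.28 and -2.29, CDK8 at -1.72 and -1.68 and MED7 at -1.12 and -1.67. Mediator genes had camera adjusted p = 0.000236 and 0.000899 (adjusted p = 0.166 and 0.181 with an estimated correlation). Of 23 pausing and elongation factor genes 6 and 7 fell, 7 and 7 adjusted over the list alone. MEPCE, which caps the noncoding RNA that holds P-TEFb inactive, was at -2.28 and -2.06, BRD2 at -1.67 and -1.53 and CDK13 at -2.07 with actinomycin D. The 5 probe sets of CDK13 ran from -2.07 to 0.30 with actinomycin D, 2 of them below 0. Elongation genes had camera adjusted p = 0.00101 and 0.00612 (adjusted p = 0.139 and 0.169 with an estimated correlation). Of 22 general transcription factor genes 5 fell and 3 rose with actinomycin D and 4 fell and 1 rose with triptolide, or 6 and 3, and 5 and 1, adjusted over the list alone. TAF5 was at -2.23 and -2.08, TAF7 at -2.09 and -1.75 and TAF4 at -1.65 and -1.90. The other probe set of TAF4 was at 0.25 and 0.12. General factors had camera adjusted p = 0.0316 and 0.0317 (adjusted p = 0.304 and 0.266 with an estimated correlation). TFIIH, the complex triptolide binds, had 9 measured genes. With actinomycin D 3 of them fell and 1 rose, 4 and 1 adjusted over the list alone, with CDK7 at -1.71, ERCC3 at -0.66 and MNAT1 at -0.56. With triptolide 1 fell, CDK7 at -1.80, and 1 rose, GTF2H5 at 0.60, or 2 and 1 adjusted over the list alone. GTF2H5 turned to -0.0059 under r2 centring and -0.42 under original hybridization centring. TFIIH genes had camera adjusted p = 0.0401 and 0.272, and with actinomycin D adjusted p = 0.304 with an estimated correlation. RNA polymerase II subunits held 1 lower gene of 11 with each drug, 1 adjusted over the list alone, POLR2D at -0.57 and -0.61 (camera adjusted p = 0.603 and 0.442).

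Splicing and decay genes were taken by family. Of 13 SR protein genes 4 and 7 fell and 1 rose with each drug, or 7 and 9 lower and 1 higher adjusted over the list alone. SRSF7 was at -0.75 and -0.97 and SRSF4 at -0.68 and -0.96, while SRSF9 rose by 0.58 with actinomycin D. SR genes had camera adjusted p = 0.00231 and 0.000233 (adjusted p = 0.304 and 0.266 with an estimated correlation). SRSF7 with actinomycin D turned to 0.11 without probe sets ending in _x_at or _s_at. Among 13 CDC-like and DYRK kinases, which phosphorylate SR proteins among other targets, 3 and 4 fell, 3 and 5 adjusted over the list alone. CLK4 was at -1.99 and -2.21 and DYRK2 at -1.27 and -1.40. Kinases of this list had camera adjusted p = 0.0157 and 0.00204 (adjusted p = 0.166 and 0.0875 with an estimated correlation). Without probe sets ending in _x_at or _s_at the kinases did not pass (adjusted p = 0.605 and 0.905). Among 22 hnRNP genes 1 and 2 fell, with equal counts adjusted over the list alone (camera adjusted p = 0.964 and 0.854). They were HNRNPF at -0.62 with actinomycin D, and with triptolide HNRNPDL at -0.51 and HNRNPA1P33, a pseudogene taken in by the name pattern, at -0.54. Of 40 mRNA decay factor genes 10 fell and 2 rose with actinomycin D and 9 fell and 1 rose with triptolide, or 10 and 6, and 9 and 1, adjusted over the list alone. TOB1, which recruits a deadenylase, led them, before CNOT8 at -1.02 and ZFP36L1 at -1.52 with actinomycin D, the latter at 0.22 without probe sets ending in _x_at or _s_at. Decay genes had camera adjusted p = 0.0153 and 0.106, and with actinomycin D adjusted p = 0.43 with an estimated correlation. Of 6 snoRNA host and similar noncoding genes 1 fell with each drug, EIF4A2 at -1.28 and -2.20, or 2 and 1 adjusted over the list alone. Host genes had camera adjusted p = 0.0348 and 0.0302 (adjusted p = 0.263 and 0.266 with an estimated correlation).

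Cell cycle and ribosome biogenesis genes stood lower as well. Of 34 G2/M genes 19 and 16 fell and none rose, 21 and 19 adjusted over the list alone. The centromeric histone gene CENPA was at -2.03 and -2.90, TTK at -1.64 with both drugs and the mitotic kinase gene AURKA at -1.95 and -1.96. AURKA was at -0.09 and -0.10 without probe sets ending in _x_at or _s_at. G2/M genes had camera adjusted p = 1.44e-12 and 1.86e-09 (adjusted p = 0.26 and 0.266 with an estimated correlation). Among 29 G1/S genes 9 fell with each drug, 9 adjusted over the list alone, where 1 was higher with actinomycin D. E2F3 was at -2.11 and -1.80 and the cyclin gene CCNE2 at -1.67 and -1.85. G1/S genes had camera adjusted p = 2.49e-05 and 0.00113 (adjusted p = 0.304 and 0.42 with an estimated correlation). Of 34 ribosome biogenesis genes 13 and 8 fell, or 14 lower, and 10 lower and 1 higher, adjusted over the list alone. WDR43 was at -3.15 and -2.81 and POLR1C, a subunit of RNA polymerases I and III, at -2.41 and -2.67. Biogenesis genes had camera adjusted p = 2.07e-07 and 0.000205 (adjusted p = 0.204 and 0.266 with an estimated correlation).

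Stress response genes gave mixed lists. Of 18 heat shock genes 6 fell with each drug, 6 adjusted over the list alone, and with actinomycin D 1 rose, 2 adjusted over the list alone. The co-chaperone gene DNAJB1 was at -2.62 and -2.54, HSPA1B at -1.16 and -0.95 and BAG3 at -1.35 and -0.87. Heat shock genes had camera adjusted p = 0.0139 and 0.0105 (adjusted p = 0.159 and 0.115 with an estimated correlation). In the unfolded protein response 7 of 22 genes fell with each drug, 8 and 7 adjusted over the list alone, and 1 and 2 rose, 3 and 4 adjusted over the list alone. DNAJB9 was at -3.24 and -3.45, XBP1 at -2.37 and -2.57 and TRIB3 at -2.31 and -2.54. Unfolded protein genes had camera adjusted p = 0.0105 and 0.00271 (adjusted p = 0.304 and 0.266 with an estimated correlation). With actinomycin D their median was 0.10, opposite in sign to their mean of -0.44 and to camera's direction. Of 14 circadian clock genes 3 fell with each drug, 3 adjusted over the list alone, PER2 at -2.69 and -2.60 (other probe set 0.11 and -0.05), and with triptolide BHLHE40 at -0.99 and NFIL3 at -0.98. Clock genes had camera adjusted p = 0.145 and 0.0459, and with triptolide adjusted p = 0.179 with an estimated correlation. Their median with actinomycin D, 0.09, differed in sign from their mean of -0.24.

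Genes of oxidative phosphorylation and lysosomes stood higher than other genes with both drugs, and those of glycolysis with triptolide. Of 71 nuclear genes of oxidative phosphorylation 12 and 13 rose and none fell, 15 and 22 adjusted over the list alone, with median changes of 0.27 and 0.30. With triptolide NDUFA10 rose by 0.72, NDUFS7 by 0.70 and ATP5MC1 by 0.69, each below 0 under original hybridization centring. With actinomycin D ATP5MC2P1, a pseudogene taken in by the name pattern, rose by 0.73, COX7A1 by 0.59 and NDUFB3 by 0.56. Oxidative phosphorylation had camera adjusted p = 0.000133 and 1.59e-09 (adjusted p = 0.432 and 0.266 with an estimated correlation). Of 25 lysosome genes 3 and 5 rose, or 8 higher and 1 lower, and 9 higher, adjusted over the list alone. Cathepsin B (CTSB) was at 0.70 with actinomycin D, MAN2B1 at 0.60 and 0.79, and HEXA at 0.73 with triptolide, but at -0.22 without probe sets ending in _x_at or _s_at. Lysosome genes had camera adjusted p = 0.0458 and 0.000227 (adjusted p = 0.541 and 0.282 with an estimated correlation). Among 17 glycolysis genes 4 rose with triptolide, 6 adjusted over the list alone, ALDOC at 0.86, PKM at 0.70 and GPI at 0.63, and none passed with actinomycin D. Glycolysis genes had camera adjusted p = 0.102 and 0.00128, and with triptolide adjusted p = 0.277 with an estimated correlation.

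Genes of protein synthesis gave other results. Of 63 ribosomal protein genes RPL37A alone rose with each drug, 1 adjusted over the list alone, and RPL36AL fell by 0.47 with actinomycin D but not when adjusted over the list alone. Ribosomal proteins had camera adjusted p = 0.577 and 0.0324, the latter upward and at adjusted p = 0.674 with an estimated correlation. It did not pass without probe sets ending in _x_at or _s_at (adjusted p = 0.954). Of 50 mitochondrial ribosomal protein genes 9 fell and 1 rose with actinomycin D and 4 fell and 5 rose with triptolide, or 9 and 2, and 5 and 7, adjusted over the list alone. With actinomycin D MRPS30 was at -2.09 and MRPL46 at -1.91. Mitochondrial ribosomal proteins had camera adjusted p = 0.0244 and 0.694, and with actinomycin D adjusted p = 0.589 with an estimated correlation. Of 32 translation factor genes 5 fell with actinomycin D, 3 adjusted over the list alone, and 3 fell and 2 rose with triptolide, with equal counts adjusted over the list alone. With actinomycin D EIF5A was at -1.24, EIF5 at -0.87 and EIF2S2 at -0.74, and EIF5 and EIF2S2 were at 0.13 and 0.14 without probe sets ending in _x_at or _s_at. Translation factors had camera adjusted p = 0.0481 and 0.694, and with actinomycin D adjusted p = 0.47 with an estimated correlation.

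**Figure D3:**
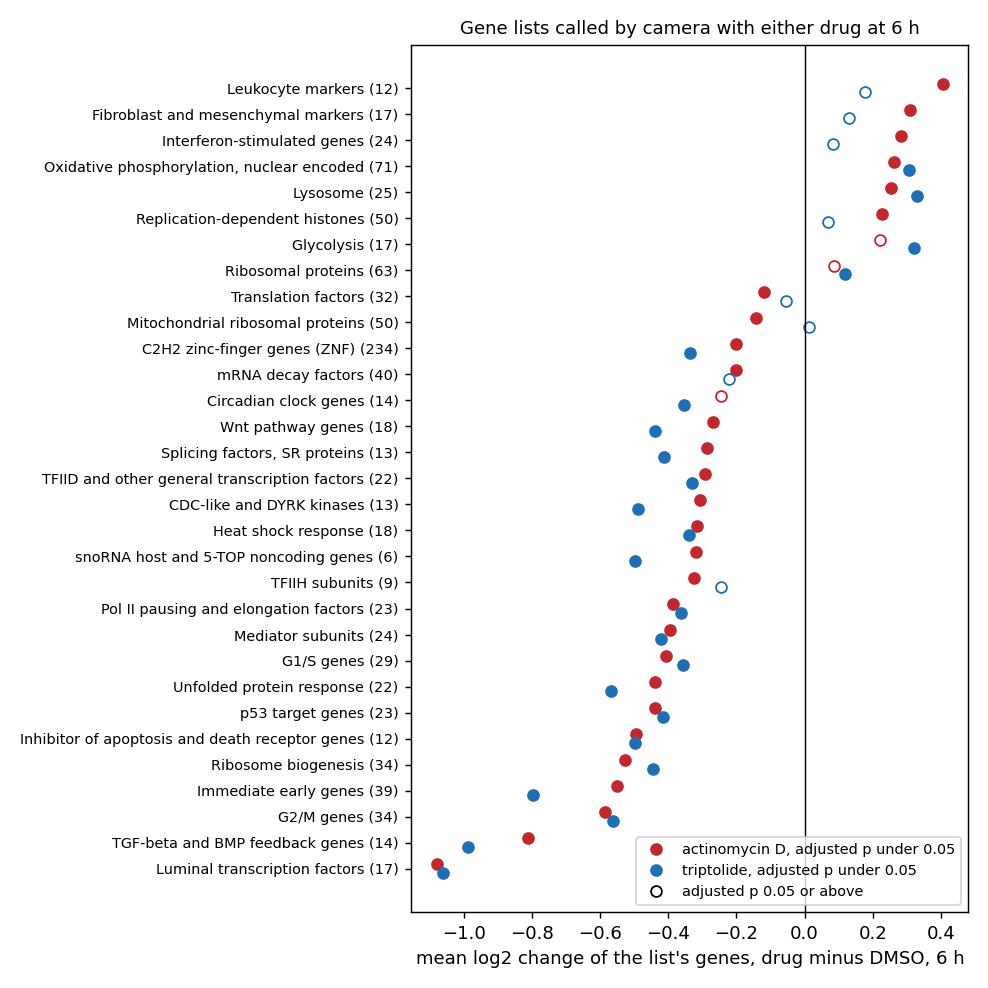
Mean log2 change at 6 h of the 31 gene lists that passed camera with either drug, with the number of measured genes in parentheses, filled points for adjusted p under 0.05 and open points otherwise. Luminal transcription factors had the lowest mean changes, -1.08 and -1.06, and the oxidative phosphorylation means were 0.26 and 0.31.

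Histone genes, interferon-stimulated genes and leukocyte and fibroblast markers stood higher with actinomycin D, and endothelial markers did not pass. Of 50 replication-dependent histone genes 5 rose and 1 fell with actinomycin D and 1 rose and 1 fell with triptolide, or 3 and 1, and 1 and 1, adjusted over the list alone. With actinomycin D H3C7 was at 0.66, H2BC9 at 0.52 and H4C3 at -0.68. Histone genes had camera adjusted p = 0.0139 and 0.267, and with actinomycin D adjusted p = 0.263 with an estimated correlation. Among 24 interferon-stimulated genes 4 and 0 rose by limma's test, with equal counts adjusted over the list alone, ISG20 at 0.51, TAP1 at 0.49 and IFI44 at 0.48. Interferon-stimulated genes had camera adjusted p = 0.0139 and 0.352, and with actinomycin D adjusted p = 0.304 with an estimated correlation. Of 12 leukocyte markers 4 rose with actinomycin D, 7 adjusted over the list alone, CD14 at 0.69, PTPRC at 0.62 and CD68 at 0.55. Of 17 fibroblast and mesenchymal markers 4 and 1 rose, 4 and 1 adjusted over the list alone, with LUM at 0.72 and THY1 at 0.45 (lowest probe set -0.03) for actinomycin D. Leukocyte markers had camera adjusted p = 0.0144 and 0.164 and fibroblast markers 0.0133 and 0.168, and with actinomycin D both had adjusted p = 0.304 with an estimated correlation. Of 7 endothelial markers 1 rose with actinomycin D, 1 adjusted over the list alone, ENG at 0.69 (camera adjusted p = 0.178 and 0.341). On the same arrays the GAPDH 3′ to 5′ difference was 0.276 higher with actinomycin D than with DMSO, and the interquartile range of gene values was 2.54 against 2.85.

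The remaining lists did not pass camera at 6 h with either drug. Of 5 antiapoptotic BCL2 family genes MCL1 and BCL2 fell with actinomycin D and MCL1 with triptolide, or 2 lower and 2 higher, and 1 lower, adjusted over the list alone (camera adjusted p = 0.191 and 0.119). Proapoptotic family genes had camera adjusted p = 0.603 and 0.854. Among NF-kB targets (0.586 and 0.345) NFKBIA, an inhibitor of the pathway, was at -1.95 and -2.15. Of 36 estrogen receptor targets (0.0666 and 0.36) 8 fell and 5 rose with actinomycin D and 6 fell and 5 rose with triptolide, or 9 and 7, and 7 and 6, adjusted over the list alone. IRS1, an adaptor of insulin signalling, was at -3.59 and -3.79. Among cholesterol synthesis genes (0.0617 and 0.396) INSIG1 was at -1.74 and -2.21. Among hypoxia targets (0.111 and 0.135) VEGFA was at -1.84 and -2.23. After quantile normalization of probe sets, where the brightest probe set was picked anew, it was at 0.37 and 0.25. As deposited its 4 probe sets already ran from -1.84 to 0.39 and from -2.23 to 0.18, so another probe set may account for the sign. Among Notch and HES genes (0.0574 and 0.102) MAML1 was at -1.74 with actinomycin D and HES1 at -1.26 with triptolide. DNA topoisomerases had camera adjusted p = 0.362 and 0.267, with TOP2A at -0.60 and -0.92, and DNA repair genes 0.178 and 0.518. Proteasome genes had 0.362 and 0.267, aminoacyl-tRNA synthetases 0.729 and 0.341, epithelial keratins and junctions 0.912 and 0.468, and cytoskeleton genes 0.191 and 0.854. With actinomycin D medians were above 0 and means below it for the antiapoptotic, NF-kB, estrogen receptor, cholesterol, hypoxia, DNA repair and topoisomerase lists. With triptolide this held for the proapoptotic, NF-kB, estrogen receptor, hnRNP, cholesterol and translation factor lists. For proteasome, synthetase, RNA polymerase II, hnRNP and epithelial genes with actinomycin D both were above 0 while camera's direction was downward.

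Triptolide was then set against actinomycin D, to which it is not structurally related, at equal times. PPM1D was 5.77-fold higher with triptolide at 2 h and 2.53-fold higher at 6 h. At 6 h the corepressor gene CDYL was 3.44-fold higher with triptolide, MRTFB, a coactivator of SRF, 2.98-fold and the phosphatase gene PTPRO 2.94-fold. SEMA4C was 3.34-fold lower, the cyclin gene CCNL1 2.61-fold and KHDC4 2.59-fold. In limma's test 1 gene differed at 2 h, 22 at 4 h (16 higher and 6 lower with triptolide), 40 at 6 h (22 higher and 18 lower) and 96 over the 3 times (79 higher and 17 lower). At an unadjusted p under 0.05 there were 545, 527 and 1921 at 2, 4 and 6 h.

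In log2 units PPM1D differed by 2.53 at 2 h (95% interval 2.14 to 2.92, adjusted p = 8.3e-07) and by 1.34 at 6 h (0.95 to 1.72, adjusted p = 0.00203). With only the arrays compared the 2 h difference had adjusted p = 0.108. At 6 h CDYL differed by 1.78 (1.33 to 2.24), MRTFB by 1.58 (1.14 to 2.02) and PTPRO by 1.55 (1.31 to 1.80, adjusted p = 1.19e-06). GABPB1 and GRHL2 were each higher by 1.04, the acetyltransferase gene KAT6B by 0.999 and the pseudogene USP32P2 by 0.998. Other probe sets of KAT6B with a mean level over 5 were at 0.276, -0.0218 and -0.0563 and that of GABPB1 at 0.229 (SE 0.18), while those of CDYL were at 0.638 and 1.17. Lower with triptolide were SEMA4C at -1.74 (-2.07 to -1.41, adjusted p = 1.59e-05), CCNL1 at -1.38 (-1.76 to -0.9998) and KHDC4 at -1.37 (-1.83 to -0.91). FEM1B followed at -0.98, the helicase gene EIF4A2 at -0.92, the stress factor gene ATF4 at -0.88, CENPA at -0.87 and LOC155060 at -0.84. Against DMSO at 6 h, the other probe set of SEMA4C was at -1.07 with actinomycin D and -1.13 with triptolide. That of PTPRO was at 0.17 and 0.10 and that of CENPA at -0.38 and -0.15, so each of these differences rests on 1 probe set. BCL2 was higher with triptolide by 0.98 at 6 h (0.65 to 1.31, adjusted p = 0.0067), but by 0.24 as the mean of its probe sets (adjusted p = 0.25). GATA3 was lower at -0.70 (-0.98 to -0.41, adjusted p = 0.0272), but at -0.02 without probe sets ending in _x_at or _s_at (adjusted p = 0.969).

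MCL1, IER3, ZNF217, SLC38A2 and ADNP, which fell with both drugs, did not pass in the test of the difference at 6 h, while PPM1D, CENPA and GATA3, which also fell with both, passed. The interval ran from -0.64 to 0.30 for MCL1, from -0.83 to 0.16 for IER3, from -0.98 to 0.20 for ZNF217, from -0.98 to 0.14 for SLC38A2 and from -0.66 to 0.44 for ADNP. For MYC it ran from -0.76 to -0.04 (adjusted p = 0.275) and for GAPDH from -0.20 to 0.26. Of the 961 genes lower with both drugs at 6 h, 18 passed in the test of the difference and 884 (92%) had an interval of the difference within 2-fold, as had 1370 of 1406 (97.4%) at 2 h and 722 of 772 (93.5%) at 4 h. These shares are of genes chosen as lower with both drugs, a choice that favours small differences. Centring on the original hybridization controls turned the signs of CDYL, MRTFB, PTPRO, GABPB1, GRHL2, KAT6B, USP32P2, BCL2 and the 6 h difference of PPM1D, with 0 calls in limma's test. Of the genes differing at 6 h 55% were higher with triptolide, against 91.9% with poly-A centring, 0.847% with r2 centring and 67.2% after quantile normalization of probe sets. At 4 h 72.7% were higher, against 60% with poly-A centring. Leaving out single arrays moved the counts.

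**Figure D4:**
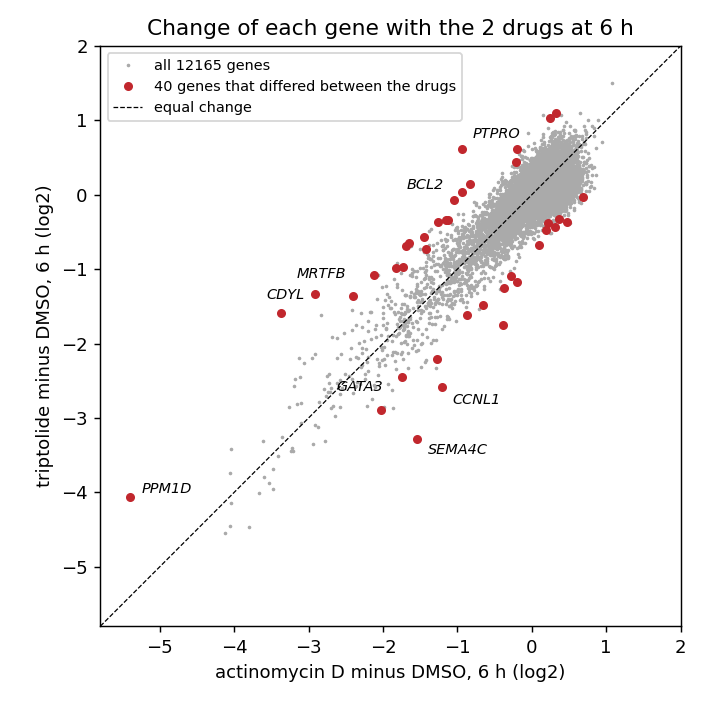
Log2 change at 6 h with triptolide against that with actinomycin D for all 12165 genes, with the line of equal change and the 40 genes that differed between the drugs in red. PPM1D lies at -5.39 with actinomycin D and -4.06 with triptolide.

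Small shifts of whole lists between the drugs passed camera, and none held with an estimated correlation. At 6 h mitochondrial ribosomal proteins were higher with triptolide by a median of 0.14 (camera adjusted p = 1.1e-05) and proteasome genes by 0.09 (0.00448). Oxidative phosphorylation genes were higher by 0.03 (0.0149), ribosome biogenesis by 0.07 (0.0149), glycolysis by 0.02 (0.0361) and lysosome by 0.07 (0.0361). Cytoskeleton genes were higher by 0.04 (0.0405), translation factors by 0.06 (0.0405) and ribosomal proteins by 0.01 (0.0421). Immediate early genes were lower at a median of -0.24 (0.00448), zinc-finger genes at -0.15 and interferon-stimulated genes at -0.21 (0.0361 each). All 12 lists had adjusted p = 0.713 with an estimated correlation. Of their members EIF5, a translation factor lower with triptolide at -0.75, passed limma's test. SR protein genes were lower with triptolide at a median of -0.18 at 2 h (camera adjusted p = 0.00201) and -0.12 at 4 h (0.0233), and hnRNP genes at -0.09 at 2 h (0.0329). These had adjusted p = 0.98 at 2 h and adjusted p = 0.996 at 4 h with an estimated correlation.

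Changes with both drugs were also compared across genes, which are not independent replicates. The log2 changes correlated at r = 0.926, 0.917 and 0.879 at 2, 4 and 6 h and at 0.95 over the 3 times (Spearman's rho 0.913, 0.787, 0.65 and 0.881). Both drugs were set against the same DMSO arrays, and 50 simulations of unchanged groups against shared controls gave mean r = 0.482, 0.484, 0.485 and 0.557. The highest simulated r was 0.831, 0.924, 0.955 and 0.916, so the observed r at 4 and 6 h lay below it. Covariances were 0.167, 0.148, 0.201 and 0.149 against simulated means of 0.0119, 0.0136, 0.0136 and 0.00516 and simulated highest values of 0.036, 0.0564, 0.0797 and 0.0211. The differences from the means, 0.155, 0.134, 0.187 and 0.144, estimate the shared effect. With different controls for the drugs, 3 DMSO arrays each, r over the 3 times ran from 0.87 to 0.922 in 8 splits and the covariance from 0.141 to 0.147. Genes lower with both numbered 1406, 772 and 961 at 2, 4 and 6 h, against 283, 74.6 and 118 for independent lists and simulated means of 0, 1.52 and 0. Genes higher with both numbered 465, 13 and 187, against 57.1, 0.741 and 43.7 for independent lists and simulated means of 0, 8.76 and 0. At 4 h the highest simulated counts, 76 lower and 438 higher, made up the whole means, so the others had none. The 13 shared rises lay below a number reached without change in that extreme alone. At all 3 times 545 genes were lower with both drugs, MCL1, MYC and GATA3 among them, and 1 was higher.

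Change over time was compared last, with 6 h set against 2 h. Relative to DMSO GATA3 fell further in this time, by 1.06 with actinomycin D (adjusted p = 0.0181) and by 1.64 with triptolide (adjusted p = 0.000209). PPM1D fell further by 1.31 with actinomycin D (adjusted p = 0.0217). With triptolide ZNF217 fell further by 1.67 (adjusted p = 0.0239), MCL1 fell by 1.08 (adjusted p = 0.0475) and HEXIM1 fell by 0.86 (adjusted p = 0.0248). In limma's test the effect of actinomycin D differed between 6 and 2 h for 111 genes (61 lower and 50 higher at 6 h) and that of triptolide for 797 (243 lower and 554 higher). Within a treatment, 883 genes differed with actinomycin D (687 higher, 196 lower at 6 h) and 3066 with triptolide (1867 higher, 1199 lower). Leaving out single arrays gave 115 to 471 with actinomycin D and 779 to 3739 with triptolide. The direction of most calls turned with actinomycin D, to 41 higher and 94 lower without replicate 2 at 2 h and 21 and 94 without replicate 2 at 6 h. Without the doubted arrays there were 326 (160 higher, 166 lower) and 759 (360 higher, 399 lower), and with only the arrays compared 74 with triptolide. In DMSO 0 genes passed limma's test, with 302 at an unadjusted p under 0.05. Genes higher at both 2 and 6 h numbered 127 with actinomycin D, against 56.9 for independent lists, and 14 with triptolide, against 43.9. Those lower at both numbered 891, against 185, and 779, against 180. The higher shares within a drug, 77.8% and 60.9%, were 54.6% and 42.5% with ribosomal protein centring, 57% and 96% with poly-A centring and 90.2% and 2.95% with r2 centring. For actinomycin D quantile normalization of probe sets gave 46.6%. The higher shares of the effects, 45% and 69.5%, were 15.7% and 43.2%, 0% and 96.5%, 98.6% and 4.23%, and 28.8% and 54.3% under these 4 scalings in turn. Leaving out single arrays moved the counts of both effects. For triptolide most calls turned lower, with 21 higher and 69 lower without replicate 2 of DMSO 6 h, 73 and 163 without replicate 2 of triptolide 2 h, 36 and 71 without replicate 2 of triptolide 6 h and 13 and 85 with the ACTB covariate. For actinomycin D 1 was higher and 17 to 25 lower without any 1 of 4 arrays, the replicate 2 arrays of DMSO and actinomycin D at 2 and 6 h, and 93 and 41 without replicate 1 of DMSO 6 h.

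Control probe sets and array measures were compared between 6 arrays of each drug and 6 of DMSO in 42 two-sided exact permutation tests over 924 splits. Alu repeat signal was lower, at a log2 difference of -0.52 with actinomycin D and -0.33 with triptolide, as was 18S ribosomal RNA signal at -1.20 and -0.80 (each exact p = 0.00216, Benjamini-Hochberg 0.013). The interquartile range of gene values was narrower, at 2.54 with actinomycin D (exact p = 0.00216, adjusted 0.013) and 2.61 with triptolide (exact p = 0.00649, adjusted 0.021) against 2.85 with DMSO. The GAPDH 3′ to 5′ difference was larger by 0.276 with actinomycin D (exact p = 0.00649) and 0.196 with triptolide (exact p = 0.00866). The ACTB difference was larger by 0.46 with actinomycin D (exact p = 0.0693, adjusted 0.127). Poly-A controls were higher by 0.256 with actinomycin D (exact p = 0.00216, adjusted 0.013) and by 0.165 with triptolide (exact p = 0.0476, adjusted 0.0909). The r2 hybridization controls were higher by 0.461 (exact p = 0.00433, adjusted 0.0165) and 0.432 (exact p = 0.00866, adjusted 0.0214).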

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

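The tests of spread, of marker genes and of the drug difference below were chosen only after the result was seen, as were their bounds, and so were the r2 controls and quantile normalization.

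Of 45 sets of 6 arrays, 5 had an array far from the other 5, and chance gives this in about 1 in 20 sets. They were the median value of actinomycin D 6 h replicate 2 (4.771), the upper quartile of triptolide 2 h replicate 2 (6.027), and the original hybridization controls of actinomycin D 6 h replicate 2 (4.05) and triptolide 2 h replicate 1 (7.554). The r2 hybridization controls of DMSO 6 h replicate 2 (10.21) completed them. Controls outside the main measurement differed from DMSO: the r2 controls by 0.461 with actinomycin D and 0.432 with triptolide, and the dim poly-A controls by 0.256 with actinomycin D. The GAPDH 3′ to 5′ difference was larger by 0.276 and 0.196, the GAPDH 3′ probe set by 0.128 and 0.119, and the 28S 3′ probe set by 0.896 with triptolide (exact p = 0.00866, adjusted 0.0214).

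Rises at 2 h with actinomycin D lay mostly among genes below the median level, 64.8% of them. After quantile normalization of probe sets this was 35.4%, so a narrower spread of values on the drug arrays may account for the share. It does not account for the rises as a whole, since 419 of the 516 genes (81.2%) were still called higher. RNA quality as measured by ACTB is argued against as the whole cause. The median change of the 516 genes was 0.4 with the ACTB covariate (interquartile range 0.325 to 0.508) against 0.53 without it (0.465 to 0.627). However, only 11 genes were still called, as the median SE grew from 0.151 to 0.196. The 9 groups accounted for 61.3% of the variance of the ACTB measure (the 3 treatments for 23.1%). Adjustment by 1 measure may be incomplete, the genes were chosen as called on these arrays, and the GAPDH 3′ to 5′ difference was not tried as a covariate. RNA quality in a wider sense therefore stays open. A rise of transcripts made by these cells cannot be told apart from background, because 27 dim markers of absent cell types had a median of 0.145 against 0.0894 for all dim genes, at percentile 84.3 of 10000 random lists, short of either bound.

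Several genes were lower with actinomycin D than with triptolide, PPM1D at 2 h by 2.529. Whether triptolide acts more slowly or weakly on all genes stays open after 3 tests, the first of which (a median of 0.028 over genes lower with both drugs at 2 h) was set aside because that choice of genes favours a value near 0. The median difference at 2 h over the 1878 genes lower with actinomycin D was 0.0872 as deposited but 0.412 with r2 centring. The ratio of triptolide to actinomycin D change was then set against that of PPM1D, raised by an allowance of 2 SE. This cut was 0.47 to 0.511 over 4 scalings, and 1.81% to 6.55% of the other genes lay at or under it. At 6 h 5.29% to 24.1% did, for the median of the 8 genes named as higher with the same allowance. The bound was 5%, and the stricter cut without the allowance was not run. That 1 probe set misread CDYL is argued against by its other probe sets, at 0.638 (SE 0.161) and 1.17 (SE 0.19), while for GABPB1 and KAT6B this cannot be told apart from a change of the gene, because 2 of only 4 other probe sets differed in the same direction. A difference between the drugs' actions on these genes was not tested and stays open.

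Alu and 18S ribosomal RNA probe sets were lower on the actinomycin D arrays. Those of 28S were not (0.173, 0.0786 and 0.038 for 5′, middle and 3′, lowest exact p = 0.225). A loss of the brightest signals is argued against, since Alu changed by -0.518 (SE 0.0604) and the lowest of 12 probe sets of similar level by -0.0251. RNA quality as measured by ACTB is argued against as well, since 18S was at -0.866 (SE 0.229) and Alu at -0.587 (SE 0.0726) with the covariate. The GAPDH difference was not tried here either. Less newly made RNA may be the source of the -0.518 of Alu, a hypothesis not itself tested, and other technical causes stay open.

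Between the drugs 1, 22, 40 and 96 genes differed at 2, 4 and 6 h and over the 3 times in a test of the difference itself. At 6 h CDYL differed by 1.784, MRTFB by 1.576, PTPRO by 1.554, PPM1D by 1.337, GABPB1 by 1.044, GRHL2 by 1.037, KAT6B by 0.999, USP32P2 by 0.9984 and BCL2 by 0.9756. Below 0 were SEMA4C at -1.74, CCNL1 at -1.381, KHDC4 at -1.372, FEM1B at -0.9758, EIF4A2 at -0.9232, ATF4 at -0.8821, CENPA at -0.8673, LOC155060 at -0.8397 and GATA3 at -0.6982. The differences of PTPRO, SEMA4C and CENPA rested on 1 of 2 probe sets. The drugs' effects differed between 6 and 2 h for 111 genes with actinomycin D and 797 with triptolide. These held GATA3 at -1.061 and PPM1D at -1.314 with actinomycin D, and GATA3 at -1.637, ZNF217 at -1.667, MCL1 at -1.085 and HEXIM1 at -0.8637 with triptolide.

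Other splits of the 12 arrays of a comparison over the 3 times, 100 of 462 drawn with the real one included, were each fitted with the time as a factor. The other splits were not held to equal numbers per time as the real one was, and the 2 arrays of a group may be technical repeats. The counts therefore speak only to the grouping of these arrays. A random grouping is argued against for actinomycin D. Only the real split (1 of 100) called as many genes there, 4827 against 2412 for the highest other. It is argued against for triptolide too, where 1 of 100 did, 2590 against 1573. Between the drugs 2 of 100 did, the real split with 61 and 1 other with 305, which exchanged actinomycin D 2 h replicate 1 and triptolide 2 h replicate 2. A split that calls several times the real count points to a structure of the samples, whose cause was not tested.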

How the results depend on the processing

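Centring on r2 controls, quantile normalization, the ACTB covariate and the fit without 2 doubted arrays were chosen after seeing the data, and the other alternatives before. Signal over background was not given for these arrays, so what it limits was not measured; of the 1217 dimmest genes 15 were called lower with actinomycin D at 2 h, against 406 of 1216 genes with a mean level of 7.472. With 2 arrays per group the median 95% interval was 0.314 log2 units to either side. The 0 calls of limma between 6 and 2 h in DMSO (302 genes at an unadjusted p under 0.05) stayed at 0 under every alternative run. Correlations of the 2 drugs' changes were 0.923, 0.929, 0.901 and 0.951 for genes above the median level, against 0.926, 0.917, 0.879 and 0.95. With different controls for the drugs the last was 0.905, where each drug also had 3 DMSO arrays in place of 6, so that the fall cannot be put down to either change. The planned log2 step was not run, as values were on that scale. For the changes below the cause was not tested unless the sentence names it.

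Centring on the original hybridization controls, which varied by an SD of 4.11 between the actinomycin D 6 h arrays, left 0 calls by limma against 2674, 1157 and 2067 with actinomycin D at 2, 4 and 6 h and 2702, 950 and 1810 with triptolide. It also left 0 between the drugs at each time and over the 3 times, for 6 against 2 h within each drug and for each drug's effect. Over the 3 times 1 gene in place of 5003 passed with actinomycin D and 3 in place of 3475 with triptolide. Single genes lost their call 212 times, and 46 changed sign. With actinomycin D at 6 h these stood at BCL2 0.0975, BHLHE40 0.1142, BIRC2 0.2919, CLK1 0.6278, CNOT8 0.1203, EIF2S2 0.4, EIF5 0.2683, ERCC3 0.482, HEXIM1 0.1015, MED7 0.02499 and MNAT1 0.586. MRPL15 was at 0.1422, MYC 0.1151, NFIL3 0.3133, POLR2D 0.5764, SQLE 0.06356, SREBF1 0.4835, SRSF4 0.4637, SRSF7 0.3972, TIGAR 0.05081 and TNFRSF1A 0.141. With triptolide at 6 h ALDOC was at -0.1643, ATP5MC1 -0.327, CTSL -0.3945, EIF3G -0.4732, EIF3I -0.4393, FASN -0.5568, GPI -0.3889, GTF2H5 -0.4181 and HEXA -0.2875. MAN2B1 was at -0.2353, NDUFA10 -0.3003, NDUFS7 -0.3176, NFATC4 -0.02188, PKM -0.3202, S100A4 -0.4624 and SLC25A1 -0.0151. Between the drugs at 6 h BCL2 was at -1.188, CDYL -0.3793, GABPB1 -1.119, GRHL2 -1.126, KAT6B -1.165, MRTFB -0.5873, PPM1D -0.8267, PTPRO -0.6094 and USP32P2 -1.165.

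Poly-A centring gave 5476 calls against 2674 with actinomycin D at 2 h, and with triptolide 5346 against 2702 at 2 h and 1038 against 1810 at 6 h. Between the drugs it gave 5 against 22 at 4 h and 52 against 96 over the 3 times. For 6 against 2 h it gave 128 in place of 883 with actinomycin D and 4850 in place of 3066 with triptolide, and for the drugs' effects 4 in place of 111 and 1360 in place of 797. Centring on the r2 controls gave 10547 with actinomycin D at 2 h and 5039 and 7775 with triptolide at 2 and 6 h. Over the 3 times it gave 9098 and 9258, and between the drugs 20 in place of 1 at 2 h, 6 in place of 22 at 4 h, 945 in place of 40 at 6 h and 55 in place of 96 over the 3 times. It gave 5314 for 6 against 2 h with triptolide, and for the effects 1212 with actinomycin D and 71 with triptolide. Under it signs changed with actinomycin D at 2 h for ACTB (-0.599), BCL2L1 (-0.575), GAPDH (-0.6831) and JUN (-0.02087). With triptolide at 6 h they changed for ACTB (-0.443), GAPDH (-0.5692), EIF3G (-0.06092), EIF3I (-0.02707), FASN (-0.1445), GTF2H5 (-0.005866) and S100A4 (-0.05015). Ribosomal protein centring gave 562 in place of 883 for 6 against 2 h with actinomycin D. Quantile normalization gave 10 between the drugs at 2 h, 64 at 6 h and 147 over the 3 times, and 236 in place of 111 for the effect of actinomycin D. Under it the brightest probe set of each gene was picked anew. VEGFA, whose 4 probe sets differed in sign as deposited, was then at 0.3738 with actinomycin D and 0.2497 with triptolide at 6 h.

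The ACTB covariate left 382 calls in place of 2674 with actinomycin D at 2 h, 214 in place of 2702 with triptolide at 2 h and 2136 in place of 5003 with actinomycin D over the 3 times. It left 911 in place of 3066 for 6 against 2 h with triptolide and 98 in place of 797 for the effect of triptolide. All 6 DMSO arrays as controls gave 4272, 1969 and 3938 with actinomycin D at 2, 4 and 6 h and 4559, 1575 and 2947 with triptolide. Without the doubted arrays (triptolide 2 h replicate 2 and actinomycin D 6 h replicate 2) there were 1368 with actinomycin D at 6 h and 357 with triptolide at 2 h. Between the drugs there were 13, 24 and 201 at 2 h, 6 h and over the 3 times. There were 326 and 759 for 6 against 2 h, and 216 for the effect of triptolide. With only the arrays compared, which leaves fewer arrays to estimate the spread, 384 passed with triptolide at 2 h and 0, 60 and 90 by limma between the drugs at 2, 4 and 6 h. For 6 against 2 h with triptolide 74 passed, and 364 and 79 for the effects of actinomycin D and triptolide. Array weights gave 35 in place of 22 between the drugs at 4 h, 1809 in place of 3066 for 6 against 2 h with triptolide and 294 in place of 111 for the effect of actinomycin D. A trended, robust variance gave 9 in place of 1 between the drugs at 2 h, and the mean of a gene's probe sets gave 2.

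A bound of at least 2-fold, which removes smaller changes, left 389, 443 and 540 with actinomycin D at 2, 4 and 6 h and 315, 358 and 508 with triptolide. Between the drugs it left 9 at 4 h and 9 at 6 h, and over the 3 times 439 and 375 with the drugs and 6 between them. It left 96 and 254 for 6 against 2 h, and for the effects 71 and 327. With only genes above the median level, and so fewer genes tested, 2707 and 2176 passed over the 3 times, and 10 lists in place of 28 and 13 in place of 23 passed camera at 6 h. With an estimated correlation 0 lists passed camera with actinomycin D and 2 with triptolide. Without probe sets ending in _x_at or _s_at, and so fewer genes tested, 735 and 1345 passed with actinomycin D at 4 and 6 h and 620 and 1154 with triptolide. Between the drugs 8 passed at 2 h and 12 at 4 h, and for 6 against 2 h 544 and 1952. Lists with actinomycin D at 6 h numbered 14 in place of 28.

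Without those probe sets, other probe sets stood for the gene. With actinomycin D at 6 h ATF6B was at -0.2026, BCL2L1 -0.7022, EIF2S2 0.1389, EIF5 0.13, FZD5 0.3204, MDM2 -0.005052, RPL37A -2.265, SRSF7 0.1105 and ZFP36L1 0.2161. At 2 h BCL2L1 was at -0.4594, MCL1 0.1322 and RPL37A -2.265. With triptolide FZD5 was at 0.09616, HEXA -0.2194 and RPL37A -2.28 at 6 h, and MCL1 at 0.03633 and RPL37A at -2.164 at 2 h. Camera, which compares means of test statistics, gave the opposite direction without a pass for CDC-like and DYRK kinases and for ribosomal proteins with triptolide, while their medians against all genes, -0.0124, -0.0517 and 0.0498, kept the sign of the earlier direction. As means of their probe sets ESR1 was at 0.07124, POLR2A at 0.06891 and RPL37A at -0.4533 with actinomycin D at 2 h. RPL37A was then at -0.5957 with actinomycin D at 6 h and at -0.561 and -0.3886 with triptolide at 2 and 6 h.

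The replicate numbers did not pair the arrays: the 36 correlations of same-number deviations between groups ran from -0.51 to 0.44, and 11 were over 0.1. A fit with the replicate block gave 2 genes in place of 1 between the drugs at 2 h, and 6 results of named genes did not pass in it. It moved no other count by over 1.5 times.

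Named genes kept their direction but lost their call 48 times with the r2 controls, 46 with the poly-A controls, 33 with the ACTB covariate, 29 without the doubted arrays and 22 as means of probe sets. They lost it 20 times without probe sets ending in _x_at or _s_at, 18 with ribosomal protein centring, 12 after quantile normalization and 8 with only the arrays compared. Calls were gained most often with the r2 controls, 17 times, and with all 6 DMSO arrays, 16 times. Lists lost their call 49 times with an estimated correlation, 28 among genes above the median level and 19 without probe sets ending in _x_at or _s_at, and fry gained 11 and lost 4.

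Where an array was left out, the lone array of a group was assumed to vary like the other groups. Calls with actinomycin D then ran from 825 to 2387 at 2 h, 612 to 1100 at 4 h, 966 to 1576 at 6 h and 3512 to 5267 over the 3 times. With triptolide they ran from 415 to 4115, 457 to 894, 1065 to 1328 and 2448 to 4166. Between the drugs they ran from 1 to 20, 4 to 9, 3 to 46 and 55 to 238. For 6 against 2 h they ran from 115 to 471 with actinomycin D, 779 to 3739 with triptolide and 0 to 0 in DMSO by limma. The effects ran from 18 to 134 and 85 to 2255, and the lists from 20 to 27 and 19 to 25. Named genes lost a call 190 times and gained one 11 times, lists 28 and 8 times.

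Arrays that moved a count by over 1.5 times follow, r1 and r2 being replicates 1 and 2. Actinomycin D at 2 h fell to 1321 and 1099 without DMSO 2 h r1 and r2 and 825 without its own r2. At 4 h it fell to 612 without DMSO 4 h r2 and 657 without its own r1, and at 6 h to 966 without DMSO 6 h r1 and 1138 without its own r2. Triptolide at 2 h went to 1121 and 916 without DMSO 2 h r1 and r2 and to 4115 and 415 without its own. At 4 h it fell to 457 without DMSO 4 h r2 and 492 without its own r2, and at 6 h to 1065 without its own r2. Between the drugs at 2 h there were 2 without triptolide r1 and 20 without r2. At 4 h there were 4 and 5 without actinomycin D r1 and r2 and 8 and 9 without triptolide r1 and r2. At 6 h there were 13 and 12 without actinomycin D r1 and r2 and 3 without triptolide r2. Over the 3 times there were 57 without actinomycin D 2 h r2, 55 without 4 h r1, 238 without triptolide 2 h r2, 56 without 4 h r1 and 59 without 6 h r2. For 6 against 2 h with actinomycin D there were 471 and 135 without 2 h r1 and r2 and 426 and 115 without 6 h r1 and r2. With triptolide there were 838 without 2 h r2 and 779 without 6 h r2. The effect of actinomycin D went to 18 and 25 without DMSO 2 h r1 and r2, 18 without DMSO 6 h r2, 29 and 26 without 2 h r1 and r2 and 54 and 25 without 6 h r1 and r2. The effect of triptolide went to 85 and 232 without DMSO 2 h r1 and r2, 90 without DMSO 6 h r2, 2255 and 236 without 2 h r1 and r2 and 107 without 6 h r2.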

Other observations

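No test in this part was chosen after its result was seen, and the lists were fixed before the data were examined. Paired values give actinomycin D before triptolide. G2/M genes stood lower than other genes already at 2 h, with 17 and 20 of 34 lower and none higher. CENPA was at -1.392 and -1.615, TTK at -1.195 and -1.127 and AURKA at -0.6834 and -0.6708. Camera gave them adjusted p = 1.76e-05 and 9.98e-08 (adjusted p = 0.522 and 0.408 with an estimated correlation). Nuclear genes of oxidative phosphorylation, with 71 measured, did not pass camera at 2 h, at medians of -0.0427 and -0.106 (adjusted p = 0.925 and 0.351). At 4 h their medians were 0.202 and 0.171 and camera placed them above other genes, at adjusted p = 2.99e-06 and 1.18e-05 (adjusted p = 0.379 and 0.422 with an estimated correlation). The change of these lists between 2 and 4 h was not tested. Fibroblast and mesenchymal markers stood higher at 2 h, with 2 and 3 of 17 higher and none lower, THY1 at 0.5007 and 0.4859 among them. They had camera adjusted p = 0.0203 and 0.00773 (adjusted p = 0.489 and 0.408 with an estimated correlation). On the same arrays the r2 hybridization controls and the GAPDH 3′ to 5′ difference were higher than with DMSO over the 3 times, by 0.461 and 0.276 with actinomycin D and 0.432 and 0.196 with triptolide.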
